A study of Homo sapiens with 17 samples.

How the data were processed

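Total RNA of L363, a human multiple myeloma cell line, was measured on 17 oligonucleotide arrays after 48 hours of culture. The cells received no drug, 0.5 uM of MS275 (MS-275, an inhibitor of class I histone deacetylases), 1 or 10 nM of rapamycin (an inhibitor of the kinase mTOR), or MS275 together with either dose of rapamycin. Per the labels' protocols, RNA was extracted with TRIzol and amplified to biotin-labelled antisense RNA. The 5 groups other than 10 nM rapamycin with MS275 hold 3 arrays each. That group holds 2, since the submitters removed 1 array at quality control per the series' design text. The labels do not say whether replicates are separate cultures, so part of the spread between arrays may be technical only.

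The values are log2 signals per probe set that the authors deposited. They were made with the affy package and RMA, per the processing tools in the labels. The versions and settings are not given in the sources used here. The values were used as deposited, with no further normalization in the reported results. The table holds 54613 probe sets. Of these, 41091 are paired with 1 gene symbol, 1801 with several and 11721 with none in the probe annotation. A RefSeq gene table (assembly GRCh38.p14) was used for names only, and 41037 of the singly named probe sets matched it by Entrez ID. A gene was represented by its singly named probe set with the highest mean over all 17 arrays, which gave 19775 genes. No detection calls or scanner files were used here, so signal over background is not known, and the number of arrays limits the precision. The median 95% confidence interval of a gene's log2 change extended 0.54 to either side between groups of 3 and 0.60 where the group of 2 took part.

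The following choices were made before the data were examined: the groups, the comparisons, the tests, the gene lists, the rule for naming genes and the alternatives, apart from those described below as chosen after seeing the data. Group means were fitted to each gene in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with default settings), with all 17 arrays in 1 model so that the 6 groups share the estimate of the spread. Each comparison was adjusted over all genes by the Benjamini-Hochberg method, and an adjusted p under 0.05 is the threshold. The comparisons are each treatment against control, the rapamycin doses against each other without and with MS275, each combination against each of its drugs alone, and the interaction, which is the combination's effect less the sum of the single-drug effects on the log2 scale. Log2 changes are given with the standard error (SE) of the fit, and group levels with the standard deviation (SD).

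The 37 gene lists cover pathways, complexes and cell types that bear on a myeloma line under these drugs, and 700 of their 782 entries were measured. Among them are markers of T cells, myeloid cells, red cells, epithelial cells, fibroblasts, B cells and plasma cells. Under 80% of the members were measured for the polyadenylated histone genes (11 of 20), red cell genes (7 of 12), ribosomal proteins (29 of 40), aminoacyl-tRNA synthetases (15 of 20), sterol synthesis genes (21 of 27) and metallothioneins (7 of 9). Lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Adjustment was over the 37 lists of a comparison. Camera compares a list's genes with all other genes. The number of members past the threshold is given with adjustment over all genes and, where said, adjusted over the list alone.

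The genes named for a comparison are the 6 largest rises and 6 largest falls past the threshold whose arrays do not overlap between the groups (without an effect, 10% of genes show no overlap with 3 arrays against 3), the 4 members of each list with the smallest adjusted p, and 24 genes of interest, such as MYC, MAX, CDKN1A, BCL2L11, AURKA and DDIT4. A gene named outside this rule is said to be so. MXD4 and H1F0, also of interest, had no singly named probe set and are not analysed here.

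Replicate numbers 1 to 3 recur in the labels of each group, with no word on whether they mark a shared day or culture. Whether they pair the arrays was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. In 7 of the 10 pairs of groups with 3 shared numbers every correlation was over 0.1, from 0.29 to 0.85. These pairs join control, MS275, 1 nM rapamycin and its combination to each other, and 1 nM to 10 nM rapamycin. The pairing thus comes from the data and not from the labels. For control and the 1 nM combination the correlations were 0.82, 0.71 and 0.57, but both replicates 1 hold a narrower range of values (see Results). Deviations cancel within a group, so an oddity shared by these arrays can make the other numbers correlate too. For this pair the check cannot tell a pairing from the narrow arrays. A fit with the replicate number as a block was run for every comparison, and its value stands beside a result where the numbers pair the arrays and the count moves by over 1.5 times.

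The alternatives were the replicate block, limma's moderation with trend and robust settings, leaving out dim genes (10628 kept), the mean of a gene's probe sets, a further quantile normalization, centring each array on its median, fitting only the groups compared, array weights, all probe sets in place of genes, a log2 change of at least 1 in addition, and leaving out each array in turn. For the lists, an estimated correlation and camera on ranks were also tried. After the data were seen, 3 further alternatives were chosen: a fit without the 2 arrays that hold a narrower range of values, the replicate block in the paired groups only, and camera on the interactions.

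The steps were tested on simulated data in which 200 of 19775 genes were changed. For MS275 against control, 34.4% of genes changed by 1 and 87.1% of those changed by 2 on the log2 scale were recovered, and 5.26% of calls were false. For the 10 nM combination against control the shares were 24.3%, 83.1% and 4.54%, and for the interaction at 1 nM rapamycin 6.8%, 63.4% and 6.45%. A list of 29 genes moved by 0.5 was called in 10 of 10 simulations, and 0 of 360 unmoved lists were called. The simulated noise was independent between genes and between arrays, with no replicate effect and no narrow arrays. The lists there were of random genes. All these shares hold only for such noise, and they cannot show how often camera calls lists of correlated genes without an effect. The 13522 probe sets with no gene symbol or several were used only where said.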

Results

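The 17 arrays comprise 3 of untreated L363 cells, 3 with 0.5 uM MS275, 3 with 1 nM rapamycin, 3 with 10 nM rapamycin, 3 with 1 nM rapamycin and MS275, and 2 with 10 nM rapamycin and MS275, all at 48 hours. Rapamycin with MS275 is called the 1 nM or the 10 nM combination here, after its dose of rapamycin. Median log2 signals ran from 5.09 to 5.36 per array. Control replicate 1 and replicate 1 of the 1 nM combination held a narrower range of values, with an SD over all probe sets of 2.14 and 2.15 against 2.27 to 2.37 on the other 15 arrays. They also had the highest medians, 5.36 and 5.35. Each correlated best with the other across probe sets (r = 0.966), and counts of changed genes are therefore also given without these 2 arrays. The first principal component held 32.4% of the variance and set these 2 arrays apart. The second held 29.3% and followed the replicate numbers in the groups of 3. Their replicates 2 had loadings from 0.11 to 0.30 and their replicates 3 from -0.32 to -0.24. Replicates 1 and 2 of the 10 nM combination lay at 0.38 and -0.31. Arrays with and without MS275 parted on the third component, which held 14.7%. The reported fit has no term for the replicate number.

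**Figure D1:**
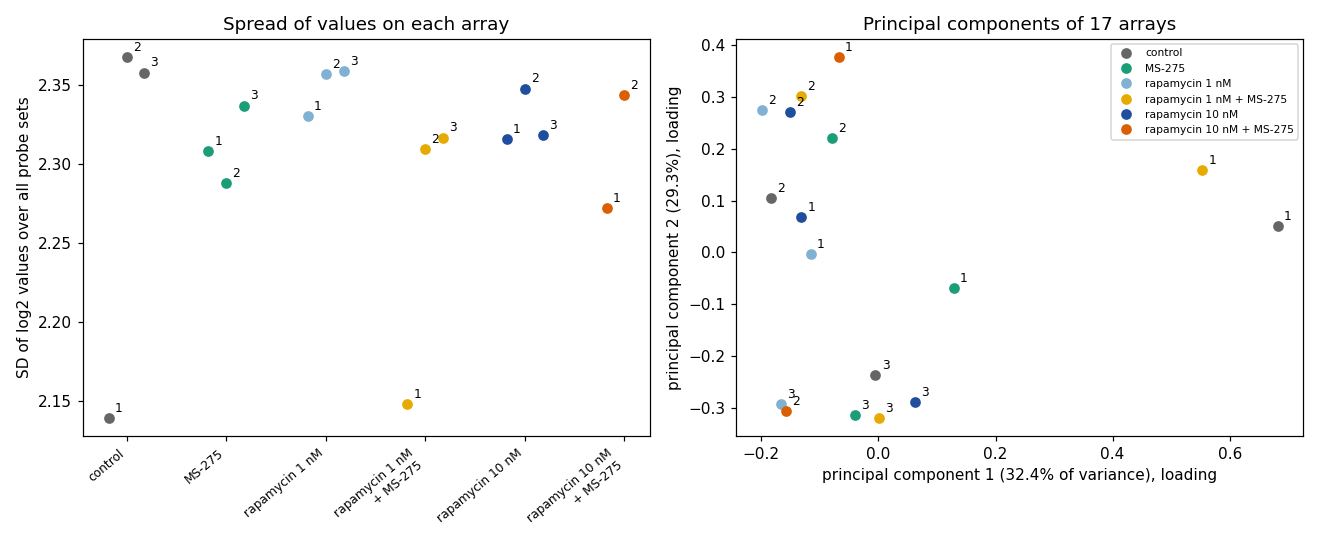
The left panel plots the SD of the log2 signals on each array by group, and the right panel the loadings of the 17 arrays on the first 2 principal components; numbers beside points are replicate numbers. Control replicate 1 (SD 2.14) and replicate 1 of the 1 nM combination (SD 2.15) lie below the other 15 arrays and far along the first component.

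MYC, the transcription factor whose protein level the series title addresses, had a log2 signal of 12.01 ± 0.38 (SD, n = 3) in control cells. Its RNA did not pass the threshold in any treatment. The log2 change from control was 0.22 ± 0.27 with MS275, 0.27 ± 0.27 with 1 nM rapamycin, 0.47 ± 0.27 with 10 nM, 0.55 ± 0.27 in the 1 nM combination and 0.44 ± 0.30 in the 10 nM combination (SE), with limma adjusted p from 0.418 to 0.871. BCL2L11, which encodes the cell death activator BIM, rose by 1.41 ± 0.29 with MS275 and by 1.61 ± 0.29 and 1.91 ± 0.33 in the combinations, while its 1.03 ± 0.29 and 1.15 ± 0.29 with rapamycin alone missed the threshold (at 1 nM adjusted p = 0.048 with the replicate block). AURKA, a mitotic kinase, fell by 1.17 ± 0.26 with MS275, by 1.81 ± 0.26 with 10 nM rapamycin, and by 1.89 ± 0.26 and 2.12 ± 0.29 in the combinations (with 1 nM rapamycin the change was -1.31 ± 0.26, adjusted p = 0.0825, and adjusted p = 0.0161 with the replicate block). With MS275 the AURKA call was lost, for example, without control replicate 2 or 3 or any array of MS275 or 1 nM rapamycin. At 10 nM rapamycin it was lost without control replicate 3 or 10 nM rapamycin replicate 1. The BCL2L11 call with MS275 was lost without control replicate 1 or 3 or MS275 replicate 2 or 3. CDKN1A, the cell cycle inhibitor p21, passed in no comparison with control (log2 changes of 0.82, -1.75, -1.81, -0.24 and -0.72 in the order above). At 1 nM rapamycin it passed with the replicate block (adjusted p = 0.0465), and without control replicate 2 it passed at both doses (-2.23 and -2.29). In MS275-treated cells the drug's targets HDAC1, HDAC2 and HDAC3 differed from control by -0.26, -0.12 and 0.05, none past the threshold, though HDAC1 passed without the 2 narrow arrays (-0.65, adjusted p = 0.0186).

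**Figure D2:**
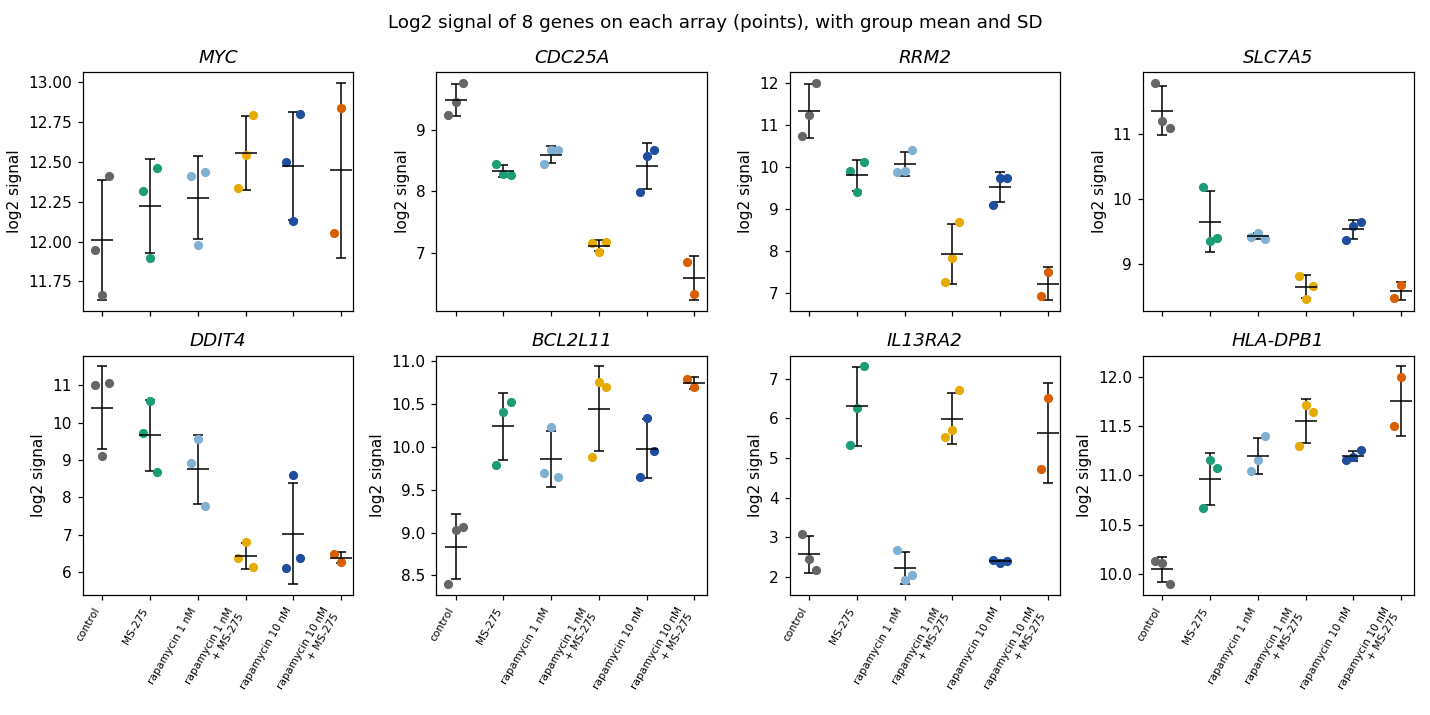
Log2 signal of 8 genes on each array (coloured points, by group), with the group mean (horizontal bar) and SD (error bar; 3 arrays per group, 2 for the 10 nM combination); the vertical axes have separate ranges that do not start at 0. MYC, with a control mean of 12.01, passed the threshold in no treatment, and RRM2, CDC25A and SLC7A5 lay lowest in the combinations.

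MS275 against control asks what the histone deacetylase inhibitor changed by itself. Among the largest rises past the threshold, CA2, a carbonic anhydrase, rose by 4.22 ± 0.73 on the log2 scale (18.6-fold), IL13RA2, an interleukin 13 receptor chain, by 3.73 ± 0.50 from a control level of 2.56 ± 0.47 (SD, n = 3), and HEY1, a Notch target, by 3.43 ± 0.59. DAZL, a germ cell RNA-binding protein, GJA1, a gap junction protein, and the neuronal MAP2 rose by 3.45, 3.43 and 3.30. The largest falls were in NRROS (-2.07 ± 0.26), the co-repressor CBFA2T3 (-1.77 ± 0.22), MYEOV (-1.74 ± 0.39), BDH1 (-1.70 ± 0.18) and SLC7A5 (-1.70 ± 0.23), the last of which is a subunit of the large amino acid transporter with SLC3A2 (-1.48 ± 0.31).

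Of 29 measured genes of DNA replication and the G1/S step, 5 fell, 0 rose and 24 did not pass (9 fell adjusted over the list alone). They included MCM4 (-1.47 ± 0.21) and MCM5 (-1.37 ± 0.28), subunits of the replicative helicase, and the phosphatase CDC25A (-1.15 ± 0.20). Their median change was -0.60 (camera adjusted p = 4.18e-08, but adjusted p = 0.41 with an estimated correlation). Among 26 mitotic genes 3 fell (7 adjusted over the list alone), such as MKI67 (-1.32 ± 0.20) and PLK1 (-1.38 ± 0.30), with a median of -0.56 (adjusted p = 5.16e-07, and 0.41 as adjusted p with an estimated correlation). Of 40 MYC target genes of growth and ribosome assembly 5 fell and 0 rose (12 fell adjusted over the list alone), among them the folate carrier SLC19A1 (-1.15 ± 0.20), the pyrimidine enzyme CAD (-1.09 ± 0.21) and the nucleolar NOLC1 (-0.93 ± 0.17); the median was -0.46 (adjusted p = 3.45e-09, and adjusted p = 0.41 with an estimated correlation). Of 33 genes of the ATF4 amino acid response 3 fell (5 adjusted over the list alone), with a median of -0.53 (adjusted p = 4.69e-07, and adjusted p = 0.249 with an estimated correlation). Of 12 MHC class II genes 2 rose, HLA-DMA (1.00 ± 0.18) and HLA-DPB1 (0.92 ± 0.19), and 8 rose adjusted over the list alone, with a median of 0.88 (adjusted p = 1.55e-09, and adjusted p = 0.111 with an estimated correlation). Of 17 genes known to rise with such inhibitors in many cell lines 1 passed, the actin-severing GSN (2.11 ± 0.26); the list's median was 0.34 (adjusted p = 0.00355, and adjusted p = 0.42 with an estimated correlation), and without control replicate 2 the list no longer passed (median 0.10).

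In limma 295 genes changed, 205 higher and 90 lower, and 15 lists shifted, 6 higher and 9 lower, of which 0 passed with an estimated correlation. Leaving out the 2 narrow arrays gave 531 genes, 288 higher and 243 lower, of which 257 were among the 295, and array weights gave 772 higher and 732 lower, so the share of rises was smaller in both. The replicate block gave 662, including all 295 in the same direction. The count was 157 without control replicate 3, and 181, 164 and 97 without MS275 replicates 1, 2 and 3; 8 of 28 gene changes followed by name passed with every array left out in turn, namely IL13RA2, NRROS, CBFA2T3, BDH1, SLC7A5, GSN, MCM4 and MKI67. With only the MS275 and control arrays in the fit 9 genes passed, all higher.

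Rapamycin against control asks what mTOR inhibition changed by itself at each dose. Both doses lowered INHBE, an activin subunit, the most, by 3.40 ± 0.51 at 1 nM (10.6-fold) and by 3.85 ± 0.51 at 10 nM (14.4-fold) on the log2 scale, and the cystine transporter SLC7A11, by 2.47 ± 0.38 and 2.49 ± 0.38. The amino acid transporter pair SLC7A5 (-1.91 at 1 nM and -1.81 at 10 nM) and SLC3A2 (-1.85 and -1.65) fell too. The plasma cell surface enzyme CD38 fell by 1.49 ± 0.20 and 1.36 ± 0.20, and the lysosomal sialidase NEU1 by 1.42 ± 0.18 and 1.20 ± 0.18. Rises were fewer: the histone gene H2BC12 rose by 2.23 ± 0.34 and 2.24 ± 0.34, DENND2C at both doses (by 1.81 ± 0.31 at 1 nM), SH3YL1 by 1.35 and 1.29, and the MHC class II gene HLA-DPB1 by 1.16 ± 0.19 at both doses. At 10 nM RASGRP3 and COMMD6 rose as well, by 1.94 ± 0.29 and 1.41 ± 0.28.

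Genes of cell division, amino acid supply and sterol synthesis lay lower and MHC class II genes higher at both doses. Of 26 mitotic genes 1 fell at 1 nM and 8 at 10 nM (11 and 16 adjusted over the list alone). Examples were MKI67 (-1.51 ± 0.20 and -1.87 ± 0.20) and, at 10 nM, CDC20 (-2.03 ± 0.29), PLK1 (-1.99 ± 0.30) and AURKB (-1.63 ± 0.24). The list's medians were -0.80 and -1.26, with camera adjusted p of 1.89e-09 and 2.21e-24, and adjusted p of 0.347 and 0.0344 with an estimated correlation. Of 29 G1/S and replication genes 1 fell at 1 nM and 5 at 10 nM (7 and 13 adjusted over the list alone). MCM4 fell at both doses (-1.35 ± 0.21 and -1.50 ± 0.21), and at 10 nM CDC45 (-1.53 ± 0.25), E2F2 (-1.87 ± 0.32) and CDC25A (-1.07 ± 0.20) were examples. The medians were -0.43 and -0.77 (adjusted p of 1.47e-05 and 4.13e-16, and adjusted p of 0.608 and 0.125 with an estimated correlation). At 1 nM the list no longer passed without control replicate 2 or 3 (medians -0.41 and -0.34). Control replicate 1 lay lower on this list than control replicates 2 and 3. Its median deviation from each gene's mean over all arrays was 0.12, against 1.18 and 1.38. On the mitotic list it was 0.015, against 1.35 and 1.36. In every comparison with control, falls on these 2 lists are therefore smaller than against replicates 2 and 3. Which control arrays are typical was not tested. Outside the lists, the transcription factor MYBL2 fell at both doses (-1.65 ± 0.22 and -2.06 ± 0.22), and among the largest falls were the condensin subunit NCAPH at 1 nM (-1.57 ± 0.25) and the mitotic CDCA8 at 10 nM (-1.99 ± 0.29).

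Of 33 genes of the ATF4 amino acid response 3 fell at 1 nM and 4 at 10 nM, where SLC1A4 (-1.63 ± 0.30) joined SLC7A11, SLC7A5 and SLC3A2. Adjusted over the list alone 13 and 15 fell, and the medians were -0.76 and -0.64 (adjusted p of 4.77e-11 and 5.83e-14). Of 21 sterol and fatty acid synthesis genes 1 fell at 1 nM, DHCR7 (-1.45 ± 0.24), and 3 at 10 nM, DHCR7 (-1.34 ± 0.24), the desaturase SCD (-1.33 ± 0.25) and FDPS (-1.13 ± 0.22). Adjusted over the list alone 7 fell at 1 nM and 7 at 10 nM, and the medians were -0.58 and -0.53 (adjusted p of 1.13e-05 and 3.19e-08). Of 12 MHC class II genes 1 rose at 1 nM and 2 at 10 nM, HLA-DPB1 and HLA-DRB1 (0.94 ± 0.18). Adjusted over the list alone 7 and 8 rose, with medians of 0.69 and 0.73 (adjusted p of 2.46e-12 and 8.91e-16). These 3 lists passed at both doses with an estimated correlation, with adjusted p of 0.0474 and 0.023, 0.00982 and 0.00188, and 0.0474 and 0.0198. The 11 genes of MYC and its MAX network partners also lay higher, with medians of 0.28 and 0.46 and adjusted p of 0.00257 and 0.000348 (0.0474 and 0.0198 as adjusted p with an estimated correlation). None of these 11 genes passed by itself over all genes (1 rose at each dose adjusted over the list alone), and array weights ended the list's call. The 29 ribosomal protein genes had medians of 0.39 and 0.39 with 0 past the threshold (adjusted p of 8.76e-19 and 2.79e-17, and adjusted p of 0.0538 and 0.0598 with an estimated correlation).

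At 1 nM rapamycin 20 genes changed in limma, 4 higher and 16 lower, and at 10 nM 86, 13 higher and 73 lower. Without the 2 narrow arrays the counts were 46 and 152, of which 18 and 68 were among those genes, and with the replicate block the 1 nM count was 112. In total 11 lists shifted at 1 nM and 13 at 10 nM, of which 4 and 5 passed with an estimated correlation. The 1 nM count was 7 without control replicate 1 or 3, 73 without control replicate 2, 0, 5 and 0 without 1 nM rapamycin replicates 1, 2 and 3, and 13 without MS275 replicate 3 or either array of the 10 nM combination. The 10 nM count was 10 without control replicate 3, 2, 46 and 18 without 10 nM rapamycin replicates 1, 2 and 3, and 41, 48 and 46 without those of 1 nM rapamycin. It was 48 and 49 without replicates 2 and 3 of the 1 nM combination, 46 without either array of the 10 nM combination and 43 without MS275 replicate 3. Of the gene changes followed by name 0 of 15 at 1 nM and 2 of 28 at 10 nM (MYBL2 and MKI67) passed with every array left out in turn. With only 1 dose and control in the fit 0 genes passed at 1 nM and 0 at 10 nM in limma, against 1592 and 1376 at an unadjusted p under 0.05 with all arrays.

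The 10 nM against the 1 nM dose asks whether more rapamycin changed more. DDIT4, a stress gene that inhibits mTOR, differed by -1.72 ± 0.69, AURKA by -0.50 ± 0.26 and MYC by 0.20 ± 0.27, none past the threshold. In limma 0 genes differed, with 24 at an unadjusted p under 0.05. That is far under the share of 0.05 of the 19775 genes expected without an effect. The test may thus be too cautious here, and the 0 does not show that the doses act alike. With the replicate block 0 genes passed as well, both with all arrays and with only the arrays of these doses. All 20 genes past the threshold at 1 nM were also past it at 10 nM in the same direction, against 0.0617 expected for independent lists. The lists share the controls and the estimate of the spread and so are not independent, and no expected overlap was made for that case. The log2 changes from control at the doses had an r of 0.93 across genes, which are not independent replicates. Both comparisons use the same control arrays, and unchanged groups simulated against them gave an r of 0.50. The covariance was 0.158 against 0.0544 in the simulations, and since the controls are too few to be divided, part of the excess can come from sharing them. The simulations also left out the pairing of same-numbered arrays of 1 and 10 nM rapamycin, whose deviations correlated at 0.31, 0.85 and 0.71. Such pairing can raise the r and covariance of unchanged groups, so the excess by itself does not show a common effect. By list, mitotic genes (median -0.51), G1/S genes (-0.35) and glycolysis genes (-0.14) lay lower at 10 nM (adjusted p of 1.12e-24, 1.2e-17 and 3.13e-07), and lysosome and autophagy genes higher (0.13, adjusted p = 0.0283). With an estimated correlation 0 lists passed (adjusted p of 0.166, 0.286, 0.286 and 0.662).

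The 10 nM against the 1 nM combination asks the same with MS275 present. MYC differed by -0.11 ± 0.30, MAX by 0.42 ± 0.39 and CDKN1A by -0.48 ± 0.48, none past the threshold. In limma 0 genes differed, with 152 at an unadjusted p under 0.05, again far under the share of 0.05 expected without an effect. The 0 thus does not show that the combinations act alike. The ribosomal proteins were the single list to shift (median 0.10, adjusted p = 0.000754, and adjusted p = 0.955 with an estimated correlation).

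The combinations against control ask what the drugs changed together. RRM2, a subunit of ribonucleotide reductase, fell (-3.40 ± 0.37 and -4.09 ± 0.42 in the 1 nM and the 10 nM combination, 10.5-fold and 17.1-fold), with CDC25A (-2.36 ± 0.20 and -2.89 ± 0.23) and MCM4 (-2.31 ± 0.21 and -3.15 ± 0.24). DDIT4 fell (-3.96 ± 0.69 and -4.01 ± 0.77), as did INHBE (-3.55 ± 0.51 and -3.41 ± 0.57) and SLC7A5 (-2.69 ± 0.23 and -2.76 ± 0.26). The largest rises included the transcription factor HEY1 (3.28 ± 0.59 and 3.74 ± 0.66), OTOGL (2.94 ± 0.36 and 3.46 ± 0.40) and TPTE2P6 (2.79 ± 0.29 and 3.28 ± 0.33). In the 1 nM combination IL13RA2 (3.42 ± 0.50), HLA-DRB4 (3.14 ± 0.34) and AHNAK (3.04 ± 0.29) were also among them, and in the 10 nM combination YPEL2 (3.41 ± 0.57), TMEM178A (3.37 ± 0.48) and MAP2 (3.19 ± 0.78). MAP2 was at 1.95 and not past the threshold without that group's replicate 2. BHLHE40 (-2.72 ± 0.61) and MCM10 (-2.70 ± 0.40) were among the largest falls at 1 nM, and E2F2 (-3.23 ± 0.36) and the lipoprotein receptor SCARB1 (-3.15 ± 0.40) at 10 nM.

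Of 29 G1/S and replication genes 17 fell in the 1 nM and 16 in the 10 nM combination (25 and 23 adjusted over the list alone). They included CDC45 (-2.40 ± 0.25 and -2.81 ± 0.28) and GINS2 (-2.01 ± 0.21 and -2.56 ± 0.24), and the medians were -1.61 and -1.62 (adjusted p of 7.64e-35 and 3.02e-26). Of 26 mitotic genes 10 and 12 fell (18 and 15 adjusted over the list alone), such as MKI67 (-1.88 ± 0.20 and -2.56 ± 0.23) and PLK1 (-1.96 ± 0.30 and -2.47 ± 0.34). Their medians were -1.42 and -1.64 (adjusted p of 1.63e-23 and 8.46e-19). Of 22 glycolysis genes 9 and 11 fell (14 in each adjusted over the list alone), with medians of -1.22 and -1.28 (adjusted p of 1.84e-17 and 4.49e-12). Examples were the glucose transporter SLC2A1 (-1.97 ± 0.27 and -1.96 ± 0.30) and the enzymes PGAM1 (-1.29 ± 0.18 and -1.43 ± 0.20) and GPI (-1.72 ± 0.25 and -1.89 ± 0.28). Of 21 sterol and fatty acid synthesis genes 7 and 8 fell (10 and 11 adjusted over the list alone), such as SCD (-2.06 ± 0.25 and -2.56 ± 0.28) and FASN (-2.57 ± 0.37 and -2.48 ± 0.41). Their medians were -0.86 and -1.01 (adjusted p of 1.45e-13 and 2.9e-10). Of 33 ATF4 response genes 11 and 12 fell (18 and 15 adjusted over the list alone), SLC3A2 among them (-2.07 ± 0.31 and -2.50 ± 0.34), with medians of -1.09 and -0.88 (adjusted p of 1.84e-17 and 8.52e-11).

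Of 12 MHC class II genes 8 rose in the 1 nM and 7 in the 10 nM combination (10 and 11 adjusted over the list alone). Examples were HLA-DPB1 (1.51 ± 0.19 and 1.71 ± 0.21), HLA-DRB1 (1.29 ± 0.18 and 1.14 ± 0.20) and HLA-DOA (1.91 ± 0.32 and 1.76 ± 0.36), and the medians were 1.21 and 1.17 (adjusted p of 4.31e-17 and 3.36e-15). With an estimated correlation, the G1/S, glycolysis, sterol, ATF4 and MHC class II lists passed in both combinations (adjusted p from 0.000158 to 0.0371). The mitotic list passed so in the 1 nM combination (adjusted p = 0.0333) but not in the 10 nM combination (adjusted p = 0.0553). Of 40 MYC target genes 3 and 7 fell (11 and 12 adjusted over the list alone), such as SLC19A1 (-1.45 ± 0.20 and -1.57 ± 0.23). Their medians were -0.52 and -0.47 (adjusted p of 3.42e-10 and 3.32e-06, and adjusted p of 0.294 and 0.651 with an estimated correlation). In the 10 nM combination the MYC targets no longer passed without that group's replicate 1 (median -0.33). Of 19 genes whose products act on MYC protein, 2 fell in each combination, AURKA and PLK1, and 1 rose, the ubiquitin ligase subunit FBXO32 (0.95 ± 0.24 and 1.15 ± 0.26). At 1 nM the FBXO32 call was lost without control replicate 2 or 3 or any array of MS275, 1 nM rapamycin or the combination. At 10 nM it was lost without control replicate 2 or 3.

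**Figure D3:**
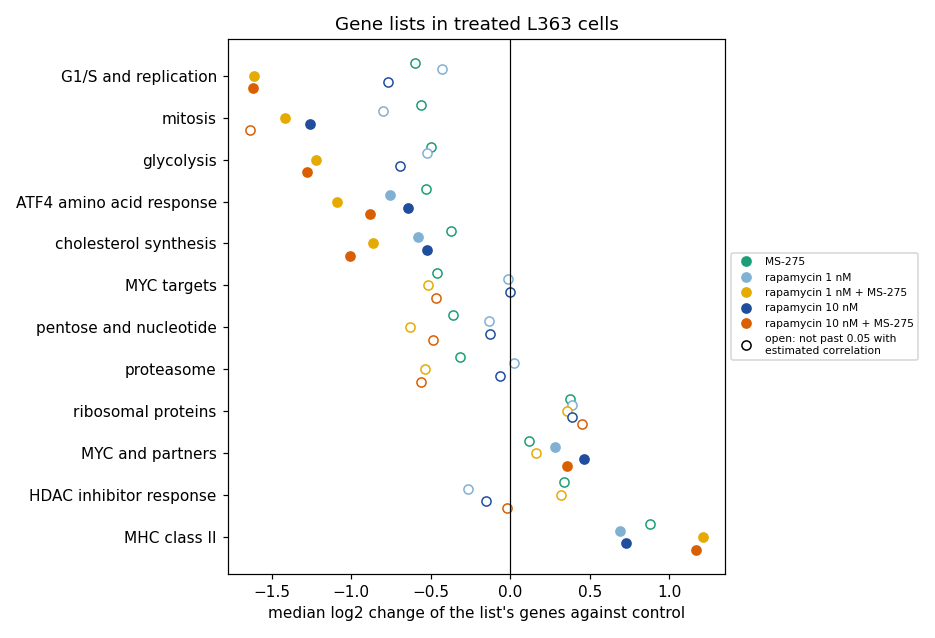
Median log2 change from control of the genes of 12 lists (horizontal axis), coloured by treatment; filled points passed camera with an estimated correlation at an adjusted p under 0.05 and open points did not. G1/S genes lie at -1.61 and -1.62 and MHC class II genes at 1.21 and 1.17 in the combinations.

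In limma 533 genes changed in the 1 nM combination, 221 higher and 312 lower, and 652 in the 10 nM combination, 209 higher and 443 lower. There 17 and 12 lists shifted, of which 6 and 6 passed with an estimated correlation. Without the 2 narrow arrays 623 and 938 genes changed, 401 and 566 of them among those above, and with the replicate block the 1 nM count was 1033. The 1 nM count was 806 without control replicate 1, 344 without control replicate 3 and 322 without the combination's replicate 2. The 10 nM count was 420 without control replicate 3 and 232 and 159 without the combination's replicates 1 and 2, and 19 lists shifted there without control replicate 1. Of the gene changes followed by name 33 of 41 and 21 of 41 passed with every array left out in turn. With only the combination and control in the fit 0 and 0 genes passed in limma, against 2495 and 2804 at an unadjusted p under 0.05 with all arrays.

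Each combination against MS275 alone asks what rapamycin added. The complement receptor C3AR1 fell (-2.29 ± 0.18 and -2.60 ± 0.20 in the 1 nM and the 10 nM combination, 4.89-fold and 6.07-fold), as did the membrane protein EMP2 (-2.16 ± 0.27 and -2.40 ± 0.30). The collagen prolyl hydroxylase P4HA1 fell (-2.31 ± 0.37 and -2.66 ± 0.42), with CD38 (-1.37 ± 0.20 and -1.80 ± 0.23) and NEU1 (-1.17 ± 0.18 and -1.67 ± 0.20). At 1 nM the cyclooxygenase PTGS2 fell (-2.13 ± 0.37), and at 10 nM RRM2 (-2.58 ± 0.42), the sterol regulator SREBF1 (-2.56 ± 0.49) and GINS4 (-2.46 ± 0.34). COQ8A was the 1 rise past the threshold at each dose (0.72 ± 0.13 and 0.91 ± 0.14). DDIT4 (-3.22 ± 0.69 and -3.27 ± 0.77) and MYC (0.33 ± 0.27 and 0.22 ± 0.30) did not pass.

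Of 29 G1/S genes 2 fell against MS275 in the 1 nM combination, GINS2 (-1.37 ± 0.21) and CDC25A (-1.21 ± 0.20). In the 10 nM combination 6 fell, among them GINS2 (-1.92 ± 0.24), CDC25A (-1.74 ± 0.23) and MCM4 (-1.68 ± 0.24), and 19 and 18 fell adjusted over the list alone. Their medians were -1.16 and -1.32 (adjusted p of 1.28e-35 and 6.86e-37). The glycolysis list (medians -0.68 and -0.72, adjusted p of 5.81e-15 and 6.33e-13) and the sterol list (-0.50 and -0.62, adjusted p of 9e-11 and 1.08e-10) shifted lower as well, with SCD at -1.66 ± 0.28 in the 10 nM combination. These 3 lists also passed with an estimated correlation, with adjusted p from 0.000464 to 0.0412. Of 26 mitotic genes 0 and 2 fell, AURKB (-1.63 ± 0.27) and MKI67 (-1.24 ± 0.23) among them, with medians of -0.78 and -1.01 (adjusted p of 1.68e-17 and 1.57e-20, and adjusted p of 0.0943 and 0.0602 with an estimated correlation). The 11 genes of the MYC and MAX network lay higher in the 10 nM combination (median 0.22, adjusted p = 0.00123, and adjusted p = 0.0347 with an estimated correlation). In total 1 list shifted higher and 10 lower in the 1 nM combination, and 3 higher and 8 lower in the 10 nM combination, of which 3 and 4 passed with an estimated correlation.

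In limma 21 genes changed in the 1 nM combination against MS275, 1 higher and 20 lower, and 50 in the 10 nM combination, 1 higher and 49 lower. Without the 2 narrow arrays 12 and 110 changed, 10 and 49 of them among those genes, and with the replicate block the 1 nM count was 44. The 1 nM count was 8, 5 and 6 without MS275 replicates 1, 2 and 3, 6, 3 and 4 without those of the combination and 11, 13 and 12 without those of 1 nM rapamycin. It was 13 and 12 without 10 nM rapamycin replicates 2 and 3 and 13 without either array of the 10 nM combination. The 10 nM count was 77 without control replicate 1, 19 and 32 without MS275 replicates 1 and 3 and 3 and 6 without the combination's replicates 1 and 2. C3AR1 passed with every array left out in turn in both, and EMP2 in the first. With only the compared groups in the fit 0 and 0 genes passed in limma, against 878 and 890 at an unadjusted p under 0.05 with all arrays. Both of these counts lie under the share of 0.05 of the 19775 genes expected without an effect. Deviations of same-numbered arrays of MS275 and the 1 nM combination correlated at 0.49, 0.63 and 0.75, which the fit without the block ignores. The test may thus be too cautious at least at 1 nM, and these counts do not tell whether further genes changed.

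Each combination against rapamycin alone asks what MS275 added. IL13RA2 rose (3.76 ± 0.50 and 3.23 ± 0.56 in the 1 nM and the 10 nM combination), with the scaffold protein AHNAK (3.49 ± 0.29 and 3.30 ± 0.32), the adhesion molecule NCAM1 (2.93 ± 0.34 and 3.39 ± 0.38) and HEY1 (2.98 ± 0.59 and 3.39 ± 0.66). CA2 rose in the first (3.73 ± 0.73) and TOX2 in the second (3.07 ± 0.46). The nucleic acid sensor ZBP1 fell (-2.14 ± 0.21 and -1.98 ± 0.23), with CBFA2T3 (-2.06 ± 0.22 and -1.83 ± 0.24) and RRM2 (-2.14 ± 0.37 and -2.30 ± 0.42), while PLAGL1 (-2.37 ± 0.52) fell in the first and BDH1 (-1.94 ± 0.20) in the second. H2BC12, which rapamycin alone raised, fell in the 1 nM combination against rapamycin (-2.01 ± 0.34). MYC (0.28 ± 0.27 and -0.03 ± 0.30) and CDKN1A (1.51 ± 0.43 and 1.09 ± 0.48) did not pass, though CDKN1A did in the first with the replicate block (adjusted p = 0.0357).

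Of 29 G1/S genes 9 fell in the 1 nM and 6 in the 10 nM combination against rapamycin (19 and 12 adjusted over the list alone). Examples were CDC25A (-1.47 ± 0.20 and -1.82 ± 0.23), GINS2 (-1.50 ± 0.21 and -1.59 ± 0.24) and MCM5 (-1.57 ± 0.28 and -1.75 ± 0.32). The medians were -1.23 and -0.92 (adjusted p of 3.16e-26 and 4.65e-22, and adjusted p of 0.073 and 0.165 with an estimated correlation). The sterol list shifted lower (medians -0.34 and -0.45, adjusted p of 7.61e-05 and 4.62e-05) and also passed with an estimated correlation (adjusted p of 0.0254 and 0.0172). FASN (-1.79 ± 0.37) and HK2 (-1.28 ± 0.20) fell in the first. GSN rose in both (1.97 ± 0.26 and 1.66 ± 0.29), and in the first the MHC regulator NLRC5 (1.49 ± 0.24) and HLA-DOA (1.53 ± 0.32) rose. By list 4 shifted higher and 17 lower in the 1 nM combination, and 2 higher and 14 lower in the 10 nM combination. The sterol list was the 1 list that passed with an estimated correlation in each.

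In limma 243 genes changed in the 1 nM combination against rapamycin, 185 higher and 58 lower, and 86 in the 10 nM combination, 59 higher and 27 lower. The share higher at 1 nM was 76.1%, and 65.0% with each array centred on its median, which shifts the median of all genes by -0.12. Without the 2 narrow arrays 265 and 262 changed, 187 and 86 of them among those genes, and with the replicate block the 1 nM count was 559. The 1 nM count was 413 without control replicate 1, 98, 112 and 80 without 1 nM rapamycin replicates 1, 2 and 3, and 121 and 140 without the combination's replicates 1 and 3. The 10 nM count was 157 without control replicate 1, 44, 38 and 32 without 10 nM rapamycin replicates 1, 2 and 3, 53 and 57 without 1 nM rapamycin replicates 1 and 3, and 16 and 11 without the combination's replicates 1 and 2. Of the gene changes followed by name 10 of 19 and 4 of 14 passed with every array left out in turn. With only the compared groups in the fit 39 and 0 genes passed in limma, against 2454 and 1452 at an unadjusted p under 0.05 with all arrays.

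The combinations were also set against both single drugs and against their sum, since the series title concerns combined inhibition. The genes past the threshold against both single drugs in the 1 nM combination were CDC25A, GINS2 and MYBL2, all 3 lower. In the 10 nM combination they were 8, all lower, namely CDC25A, GINS2, MCM4, RRM2, CENPM, EBP, FUCA2 and TUBA1B. CENPM, EBP, FUCA2, TUBA1B and, at 1 nM, MYBL2 lie outside the naming rule and were chosen after their values were seen. Leaving out the 2 narrow arrays gave 0 and 25, and with the replicate block 9 genes passed at 1 nM. The 1 nM count was 0 without any 1 array of MS275 or of the combination, 9 and 5 without control replicates 1 and 3, and 1 without any 1 array of 1 nM rapamycin or 10 nM rapamycin replicate 2 or 3. The 10 nM count was 19 without control replicate 1, 1 and 0 without the combination's replicates 1 and 2, and 3 and 5 without MS275 replicates 1 and 3. It was 5 without any 1 array of 1 nM rapamycin and 4 and 3 without 10 nM rapamycin replicates 2 and 3.

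The interaction passed in limma for 0 genes at either dose, with 916 at 1 nM and 194 at 10 nM at an unadjusted p under 0.05. Both counts lie under the share of 0.05 of the 19775 genes expected without an effect. At 1 nM 1 gene passed without control replicate 2, and at 10 nM 2 passed without replicate 2 of the 1 nM combination. For MYC the interaction was 0.06 ± 0.38 and -0.25 ± 0.40, and for DDIT4 -1.58 ± 0.97 and 0.09 ± 1.03. It was -1.10 ± 0.45 for CCND2 and -0.82 ± 0.41 for BCL2L11 at 1 nM, and 0.86 ± 0.39 for AURKA at 10 nM, none past the threshold.

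The effect of each drug was last compared without and with the other, across genes, in comparisons that share no array. The effect of MS275 had an r of 0.25 (Spearman rho 0.17) between cells without and with 1 nM rapamycin, and of 0.71 (rho 0.57) with 10 nM. Genes past the threshold in both, such as IL13RA2, HEY1 and CBFA2T3, numbered 99 higher and 29 lower at 1 nM, against 1.92 and 0.264 expected for independent lists. At 10 nM they were 52 and 16, against 0.612 and 0.123, and 0 went in opposite directions at either dose. The effect of rapamycin had an r of -0.10 (rho -0.11) between cells without and with MS275 at 1 nM and of 0.62 (rho 0.50) at 10 nM. Of genes past the threshold in both, such as CD38 and NEU1, 3 were lower at 1 nM (0.0162 expected), and 1 was higher and 21 lower at 10 nM (0.000657 and 0.181 expected). For both drugs, the calls without and with the other drug use the same estimate of each gene's spread. The lists are therefore not independent even without a common effect, and the expected numbers are too low a baseline. The r of rapamycin's effect at 1 nM was 0.44 without the 2 narrow arrays, 0.31 without control replicate 1 alone and 0.45 without replicate 1 of the 1 nM combination alone, and ran from -0.30 to -0.013 without any other array. That of MS275's effect at 1 nM was 0.71 without the narrow arrays, 0.66, 0.0014 and 0.092 without control replicates 1, 2 and 3, and 0.57, 0.14 and 0.10 without those of the 1 nM combination. The r of MS275's effect at 10 nM was 0.46 without replicate 2 of the 10 nM combination, and that of rapamycin's effect at 10 nM was 0.38.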

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

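Of the tests in this part, 6 were chosen only after the result was seen: that of a shared replicate 1 effect, both of the G1/S interaction, those of control replicate 1 and of control replicates 1 and 3 as the source of the ribosomal protein shift, and the splits within replicate numbers, and camera on the interactions was also added then.

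DNA replication genes lay lower in the combinations than the sum of the single drugs. The median interaction of the 29 G1/S genes was -0.55 with 1 nM and -0.38 with 10 nM rapamycin (camera adjusted p of 2.16e-06 and 2.94e-06, and adjusted p of 0.701 and 0.662 with an estimated correlation). The difference between groups drew attention to it, since MS275 moved these genes further with rapamycin than without. Without control replicate 1 and replicate 1 of the 1 nM combination the medians were 0.015 and 0.078, so the narrow arrays, both of them at 1 nM and control replicate 1 at 10 nM, are a candidate explanation for the whole excess. Centring each array on its median shifts the median interaction of all genes by -0.14 at 1 nM. A cooperation of the drugs on these genes was not shown by these arrays and stays open.

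Ribosomal protein genes lay higher in every treated group than in controls, with medians from 0.36 to 0.45 over the 5 comparisons and 0 of 29 genes past the threshold in limma. Without the 2 narrow arrays the smallest median was 0.41, which argues against control replicate 1 as the sole source. Against control replicates 1, 2 and 3 by themselves the medians ran from 0.18 to 0.24, 0.10 to 0.25 and 0.63 to 0.75, so replicate 3 carries much of the shift. Against replicate 2 alone they were under 0.5 times the reported ones in every comparison except the 10 nM combination (0.25 against 0.45). This leaves replicates 1 and 3 together open as the source. On this list replicate 1 lay near replicate 2, with median deviations from each gene's mean over all arrays of -0.13 and -0.09. Replicate 3 lay at -0.65. Of the 20 genes nearest in brightness to each member, other ribosomal protein genes left out, the median change was at most 0.14. This argues against a difference of scale that moves all bright genes alike. The median member lay at percentile 99.8 of all genes, so few others are as bright and the nearest can be dimmer. A difference of scale confined to the brightest genes thus stays open. A response of the ribosomal protein genes to both drugs was not shown by these arrays, and with an estimated correlation adjusted p ran from 0.0538 to 0.384.

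Control replicate 1 and replicate 1 of the 1 nM combination held a narrower range of values than the other 15 arrays. A change of scale alone leaves ranks in place, but their mean rank correlations with their group mates, 0.926 and 0.942, lay below the 0.955 of the lowest other array. Against an exchange of an MS275-treated and an untreated sample, control replicate 1 stood 8.15% of the way from its group mates to the MS275 arrays. This was over 59 genes that rose with MS275 in the 10 nM combination against 10 nM rapamycin. These genes cannot tell a control from a sample with rapamycin alone, so an exchange with such a sample was not tested. Replicate 1 of the 1 nM combination stood 87.1% of the way from 1 nM rapamycin to its group mates. Against an effect of replicate 1 shared by all groups, the deviation of control replicate 1 correlated at 0.49 and 0.35 with those of MS275 and 1 nM rapamycin but at -0.16 with that of 10 nM rapamycin. RNA quality and hybridization on these 2 arrays stay open, and no biological explanation was tested.

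Other lists also differed from the sum of the single drugs by camera. With 1 nM rapamycin the median interactions were -0.68 for oxidative phosphorylation, -0.61 for polyadenylated histones, -0.41 for the unfolded protein response, -0.39 for ribosomal proteins and -0.31 for plasma cell genes. They were -0.27 for MHC class II, -0.19 for the proteasome and -0.054 for glycolysis. With 10 nM they were -0.70 for polyadenylated histones, -0.51 for the unfolded protein response, -0.47 for oxidative phosphorylation, -0.42 for MHC class II and -0.40 for plasma cell genes. Ribosomal proteins had -0.28, mitotic genes 0.17 and the ATF4 response 0.43. With an estimated correlation adjusted p of these and the G1/S results, 18 in all, ran from 0.17 to 0.966, and none passed.

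Probe sets that the annotation gives no gene symbol or several, 13522 in all, carried signal that the comparisons of genes leave out. Past the threshold were 56 with MS275, 4 and 10 with 1 and 10 nM rapamycin, and 118 and 154 in the 1 nM and 10 nM combinations.

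Other splits of the arrays were counted for comparisons of groups of 3, where 10 splits are too few for a share under 0.05. The real split gave 295 genes with MS275, 20 with 1 nM and 86 with 10 nM rapamycin, and the highest other split 0 in each (1 of 10 splits gave as many). It gave 21 and 243 for the 1 nM combination against MS275 and against rapamycin, with a highest other of 0 in each, and 0 for 10 nM against 1 nM rapamycin, as did all 10 splits. For the 1 nM combination against control the real split gave 533 genes and another 2628, so 2 of 10 gave as many. That split sets replicates 1 and 3 of the combination and control replicate 1 against the rest, and so many genes point to a structure of the samples in which the 2 narrow arrays go together. It parts only 1 of the 3 same-numbered pairs, and the 3 other splits that part all 3 pairs gave 0 genes. A further split, replicate 1 of the combination and control replicates 1 and 3 against the rest, gave 459 genes. It also sets the narrow arrays together, and the remaining splits that do so gave 0. For lists the real split and the highest other gave 15 and 20 with MS275, 11 and 16 with 1 nM rapamycin, 13 and 16 with 10 nM, and 17 and 22 in the 1 nM combination. As many lists came from 3, 6, 6 and 3 of the 10 splits in that order. For the 3 genes past both single drugs at 1 nM, 3 of 100 drawn splits gave as many (highest other 14), and 4 of 100 that draw the groups within each replicate number (highest other 61). The count is 0 without the 2 narrow arrays, so these shares support no statement about the 3 genes. For the interaction at 1 nM all 100 splits gave at least the real count of 0 in limma, the highest 10. The real split held 916 genes at an unadjusted p under 0.05, which is under the share expected without an effect. A count of 0 is reached by any split, so this test decides nothing.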

How the results depend on the processing

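The alternatives without the 2 narrow arrays, with the replicate block in the paired groups only, and with camera on the interactions were chosen after seeing the data, and the others were planned. Where a count is given below it moved by over 1.5 times from that of the report, and for such counts the cause was not tested unless said.

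Of 211 gene changes followed by name that passed, 0 reversed under any alternative. The replicate block ended 0 of them, array weights 8, quantile normalization 15, median centring 18, leaving out the narrow arrays 23, trend and robust moderation 35, and the mean of probe sets 53. Leaving out dim genes ended 4 of 206 and the block in paired groups 2 of 113. At least 1 array left out ended 130, and fitting only the compared groups 204, where fewer arrays estimate the spread. Of followed changes that missed the threshold, the block brought 6 past it, the block in paired groups 4, array weights 7, and leaving out the narrow arrays and quantile normalization 1 each. Of 68 list results against control that passed, the estimated correlation ended 47, array weights 10, dim genes left out 9, median centring 9 and quantile normalization 8. Leaving out the narrow arrays ended 6 and reversed 2 more. The mean of probe sets ended 5, camera on ranks 4, the block 3, and trend and robust moderation and the compared groups alone 1 each. The block in paired groups ended 2 of 43, and at least 1 array left out ended 28, of which 3 also reversed without another array. Of those that missed, 19 passed without the narrow arrays and 14 with array weights, with 2 more in each that passed in the opposite direction. With the mean of probe sets 7 passed, and with quantile normalization 3. The block, the block in paired groups, camera on ranks and leaving out dim genes brought 2 each past the threshold, and the compared groups alone 1.

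Genes changed with the replicate block numbered 662 for MS275, 112 for 1 nM rapamycin, 227 for 10 nM rapamycin, 1033 for the 1 nM combination, 1343 for the 10 nM combination, 44 for the 1 nM combination against MS275, 559 for the 1 nM combination against rapamycin, 100 for the 10 nM combination against MS275, 338 for the 10 nM combination against rapamycin, 9 for past both drugs at 1 nM and 22 for past both drugs at 10 nM. With the block in the paired groups only they numbered 1001 for MS275, 224 for 1 nM rapamycin, 1490 for the 1 nM combination, 50 for the 1 nM combination against MS275, 884 for the 1 nM combination against rapamycin and 15 for past both drugs at 1 nM. By the rule of the pairing check the numbers do not pair 10 nM rapamycin with control, MS275 or the 1 nM combination. Only number 1 fell short there (r of -0.16, -0.34 and -0.19), while numbers 2 and 3 correlated at 0.18 to 0.61. The 10 nM combination shares under 3 numbers with each group. The blocked values of these comparisons thus rest on a pairing that the check did not meet in full. The replicates 1 and 2 of the 10 nM combination best matched numbers 2 and 3, and its number 2 correlated with the same number in other groups from -0.74 to 0.014, so the block sets these arrays with others than their best matches. Over all arrays 10 of 17 had their best match in an array of the same number. Trend and robust moderation gave 8 for 1 nM rapamycin, 36 for 10 nM rapamycin, 5 for the 1 nM combination against MS275, 25 for the 10 nM combination against MS275, 0 for past both drugs at 1 nM and 4 for past both drugs at 10 nM. Leaving out dim genes, so that fewer genes were tested, gave 11 for the 1 nM combination against MS275 and 1 for past both drugs at 1 nM. The mean of all probe sets gave 12 for the 1 nM combination against MS275, 2 for the interaction at 10 nM and 5 for past both drugs at 10 nM. A further quantile normalization gave 40 for 1 nM rapamycin and 2 for the interaction at 10 nM, and median centring 49 for 10 nM rapamycin and 2 for the interaction at 10 nM. Array weights, which ran from 0.114 for control replicate 1 to 11.3 for 1 nM rapamycin replicate 1, gave 1504 for MS275, 2804 for 1 nM rapamycin, 1951 for 10 nM rapamycin, 1400 for the 1 nM combination, 1555 for the 10 nM combination, 922 for the 1 nM combination against rapamycin, 325 for the 10 nM combination against rapamycin, 2 for the interaction at 10 nM, 1 for past both drugs at 1 nM and 14 for past both drugs at 10 nM. All probe sets in place of genes gave 913 for the 1 nM combination and 1121 for the 10 nM combination, since more features were tested. Without the narrow arrays there were 531 for MS275, 46 for 1 nM rapamycin, 152 for 10 nM rapamycin, 12 for the 1 nM combination against MS275, 110 for the 10 nM combination against MS275, 262 for the 10 nM combination against rapamycin, 0 for past both drugs at 1 nM and 25 for past both drugs at 10 nM, and 19 lists shifted in the 10 nM combination. With only the compared groups there were 9 for MS275, 0 for 1 nM rapamycin, 0 for 10 nM rapamycin, 0 for the 1 nM combination, 0 for the 10 nM combination, 0 for the 1 nM combination against MS275, 39 for the 1 nM combination against rapamycin, 0 for the 10 nM combination against MS275, 0 for the 10 nM combination against rapamycin and 0 for past both drugs at 10 nM, where fewer arrays estimate the spread, in limma (with all arrays the counts at an unadjusted p under 0.05 stand in the report). With an estimated correlation 0, 4, 5, 6 and 6 lists shifted for MS275, 1 nM and 10 nM rapamycin and the 1 nM and 10 nM combinations.

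With each array left out in turn the counts ran from 97 to 362 for MS275, 0 to 73 for 1 nM rapamycin, 2 to 98 for 10 nM, 322 to 806 for the 1 nM combination and 159 to 799 for the 10 nM combination. Against MS275 they ran from 3 to 31 and 3 to 77, against rapamycin from 80 to 413 and 11 to 157, past both drugs from 0 to 9 and 0 to 19, and for the interaction from 0 to 1 and 0 to 2. Lists shifted in the 10 nM combination ran from 9 to 19, the r of the MS275 effect from 0.0014 to 0.66 at 1 nM and 0.46 to 0.72 at 10 nM, and that of the rapamycin effect from -0.30 to 0.45 and 0.38 to 0.64. The group of 2 then holds 1 array, which is assumed to vary like the other groups.

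Some list medians changed sign, the cause of which was not tested. For MYC targets the medians with an array left out ran from -0.19 to 0.024 at 1 nM and -0.19 to 0.10 at 10 nM rapamycin. At 10 nM those of the proteasome ran from -0.28 to 0.050, of RNA polymerases I and III from -0.082 to 0.22, of the unfolded protein response from -0.063 to 0.29 and of aminoacyl-tRNA synthetases from -0.45 to -0.054, where the test changed direction without control replicate 3. Array weights gave -0.26 for MYC targets and -0.36 for the proteasome. Without the narrow arrays the medians were -0.19 for MYC targets, -0.28 for the proteasome, -0.082 for RNA polymerases I and III and -0.063 for the unfolded protein response, and the r of the rapamycin effect at 1 nM was 0.44. Signal over background is not known for these arrays, which limits what can be said of genes with low signals.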

Other observations

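No test in this part was chosen after the result was seen, and its values carry no explanation. Of 16 plasma cell genes CD38 fell with both doses of rapamycin and in both combinations (-0.90 ± 0.20 and -1.33 ± 0.23). In the 10 nM combination the receptor TNFRSF13B (-1.30 ± 0.31) and the syndecan SDC1 (-1.45 ± 0.37) fell too, so 3 of 16 passed. The SDC1 call was lost, for example, without any array of control or 1 nM rapamycin, and that of TNFRSF13B without control replicate 1 or 3. As a list the plasma cell genes passed with 10 nM rapamycin (median 0.33, adjusted p = 0.0209, and adjusted p = 0.363 with an estimated correlation), and the call was lost without control replicate 1 (0.27) or 10 nM rapamycin replicate 1 (0.26). Of 14 B cell genes the repressor BACH2 rose in the combinations (1.76 ± 0.40 and 2.42 ± 0.45) while the antigen receptor chain CD79B fell (-1.19 ± 0.27 and -1.38 ± 0.30). Of 10 myeloid genes CSF1R rose in the 1 nM combination (0.91 ± 0.20). The 12 T cell, 12 epithelial, 12 fibroblast and 7 red cell genes had 0 past the threshold in limma against control. Camera adjusted p of these lists, with the B cell and myeloid ones, ran from 0.154 to 0.889 over the 5 comparisons with control.

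With MS275 more lists shifted than the report describes. The interferon response, 22 genes, lay higher (median 0.21, adjusted p = 0.00423, and adjusted p = 0.41 with an estimated correlation), with IFI6 past the threshold (1.97 ± 0.39). In the 1 nM combination IFI6 rose by 2.11 ± 0.39 and the list shifted (median 0.32, adjusted p = 0.0109, and adjusted p = 0.355 with an estimated correlation), and the call was lost without control replicate 3 (0.26). Glycolysis genes lay lower with MS275 (median -0.50, adjusted p = 0.000161, and adjusted p = 0.41 with an estimated correlation), with SLC2A1 at -1.31 ± 0.27, and the call was lost without control replicate 3 (-0.42). Sterol synthesis genes lay lower (median -0.37, adjusted p = 0.00105, and adjusted p = 0.0765 with an estimated correlation), and the call was lost without control replicate 2 (-0.51). The 23 genes of the pentose phosphate path and nucleotide synthesis lay lower (median -0.36, adjusted p = 0.000737, and adjusted p = 0.621 with an estimated correlation), and the call was lost without control replicate 3 (-0.14). The 15 aminoacyl-tRNA synthetases lay lower (median -0.38, adjusted p = 0.00187, and adjusted p = 0.621 with an estimated correlation), and the call was lost without control replicate 3 (-0.13). The 27 proteasome genes lay lower (median -0.32, adjusted p = 0.0297, and adjusted p = 0.796 with an estimated correlation), and the call was lost without control replicate 2 (-0.25), control replicate 3 (-0.24), MS275 replicate 1 (-0.31) or MS275 replicate 2 (-0.15). The 7 metallothioneins lay higher (median 0.29, adjusted p = 0.0425, and adjusted p = 0.64 with an estimated correlation), and the call was lost without control replicate 2 (0.33), control replicate 3 (0.14), MS275 replicate 1 (0.23), MS275 replicate 3 (0.29) or 1 nM combination replicate 1 (0.29). Of 17 p53 targets ZMAT3 rose (1.23 ± 0.27) and the list shifted higher by camera (median 0.0036, adjusted p = 0.0374, and adjusted p = 0.484 with an estimated correlation), and the call was lost without control replicate 1 (0.085), control replicate 2 (0.060), MS275 replicate 1 (0.037) or MS275 replicate 3 (0.10).

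With rapamycin the 11 polyadenylated histone genes, H2BC12 among them, lay higher (at 1 nM a median of 0.12, adjusted p = 0.00257, and adjusted p = 0.608 with an estimated correlation, and at 10 nM 0.15, adjusted p = 0.00364, and adjusted p = 0.533 with an estimated correlation), and the call at 10 nM was lost without 10 nM rapamycin replicate 3 (0.088). At 1 nM the 25 oxidative phosphorylation genes lay higher (median 0.34, adjusted p = 0.0122, and adjusted p = 0.815 with an estimated correlation), and the call was lost without control replicate 1 (0.13), control replicate 3 (0.25) or 1 nM rapamycin replicate 3 (0.20). The 21 genes of RNA polymerases I and III and the factors of polymerase I lay higher (at 1 nM 0.072, adjusted p = 0.013, and adjusted p = 0.608 with an estimated correlation, and at 10 nM 0.093, adjusted p = 0.0312, and adjusted p = 0.686 with an estimated correlation). They no longer passed without control replicate 1 (-0.025) or 1 nM rapamycin replicate 3 (-0.023) at 1 nM, and without control replicate 1 (-0.082), 10 nM rapamycin replicate 2 (0.18) or 10 nM rapamycin replicate 3 (0.025) at 10 nM. Glycolysis genes lay lower (at 1 nM -0.53, adjusted p = 0.0225, and adjusted p = 0.644 with an estimated correlation, and at 10 nM -0.69, adjusted p = 1.01e-06, and adjusted p = 0.146 with an estimated correlation), and the call at 1 nM was lost without control replicate 3 (-0.34), 1 nM rapamycin replicate 3 (-0.47) or 1 nM combination replicate 1 (-0.53). At 10 nM the 20 genes of the unfolded protein response lay higher (median 0.18, adjusted p = 0.0409, and adjusted p = 0.643 with an estimated correlation), and the call was lost without control replicate 1 (-0.063), control replicate 3 (0.22), 10 nM rapamycin replicate 1 (0.083) or 10 nM rapamycin replicate 2 (0.18). The aminoacyl-tRNA synthetases lay lower at 10 nM (median -0.25, adjusted p = 0.0312, and adjusted p = 0.929 with an estimated correlation), and the call was lost without control replicate 2 (-0.27), control replicate 3 (-0.054), 10 nM rapamycin replicate 1 (-0.22) or 10 nM rapamycin replicate 2 (-0.26).

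In the combinations the lysosomal NEU1 fell (-1.43 ± 0.18 and -1.92 ± 0.20), as did BID, a death-promoting BCL2 relative (-1.34 ± 0.29 and -1.41 ± 0.33), while NFKBIA rose (1.63 ± 0.24 and 1.37 ± 0.27), with NLRC5 (1.23 ± 0.24 and 1.19 ± 0.27). ICAM1 fell in the 10 nM combination (-1.18 ± 0.24) and HDAC6 rose in the 1 nM combination (1.17 ± 0.23). Pentose and nucleotide genes lay lower (in the 1 nM combination -0.63, adjusted p = 3.8e-07, and adjusted p = 0.355 with an estimated correlation, in the 10 nM one -0.49, adjusted p = 0.000176, and adjusted p = 0.668 with an estimated correlation), and the call in the second was lost without control replicate 3 (-0.35) or 10 nM combination replicate 1 (-0.27). The aminoacyl-tRNA synthetases lay lower (-0.59, adjusted p = 1.84e-06, and adjusted p = 0.344 with an estimated correlation, then -0.61, adjusted p = 0.000644, and adjusted p = 0.668 with an estimated correlation), and the call in the second was lost without control replicate 3 (-0.37) or 10 nM combination replicate 1 (-0.39). Proteasome genes lay lower (-0.54, adjusted p = 2.46e-05, and adjusted p = 0.501 with an estimated correlation, then -0.56, adjusted p = 0.00502, and adjusted p = 0.907 with an estimated correlation), and the call was lost in the first without 1 nM combination replicate 1 (-0.38) and in the second without control replicate 2 (-0.45), control replicate 3 (-0.44) or 10 nM combination replicate 1 (-0.19). Ribosomal proteins lay higher in both (adjusted p of 1.28e-08 and 1.55e-12, and adjusted p of 0.27 and 0.11 with an estimated correlation). The MYC and MAX network lay higher in both (0.16, adjusted p = 0.0324, and adjusted p = 0.142 with an estimated correlation, then 0.36, adjusted p = 0.00213, and adjusted p = 0.0371 with an estimated correlation), and the call in the first was lost without control replicate 1 (0.18), 1 nM combination replicate 2 (0.27) or 1 nM combination replicate 3 (0.20).

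Some further lists passed in the 1 nM combination, and the 10 nM against the 1 nM combination showed no difference for them (camera adjusted p from 0.0988 to 0.565). There the oxidative phosphorylation genes lay lower (median -0.30, adjusted p = 0.0037, and adjusted p = 0.523 with an estimated correlation), and the call was lost without control replicate 2 (-0.10) or 1 nM combination replicate 1 (-0.17). The 17 genes known to rise with deacetylase inhibitors lay higher (median 0.32, adjusted p = 0.024, and adjusted p = 0.501 with an estimated correlation), and the call was lost without control replicate 2 (0.21), control replicate 3 (0.19), 1 nM combination replicate 1 (0.22) or 1 nM combination replicate 3 (0.082). The 21 mTOR pathway genes lay lower (median -0.13, adjusted p = 0.0324, and adjusted p = 0.314 with an estimated correlation), and the call was lost without control replicate 2 (-0.33), control replicate 3 (-0.082) or 1 nM combination replicate 1 (-0.28). The 19 genes acting on MYC protein lay lower (median -0.20, adjusted p = 0.0324, and adjusted p = 0.501 with an estimated correlation), and the call was lost without control replicate 2 (-0.17), control replicate 3 (0.12) or 1 nM combination replicate 1 (-0.050). Lists of translation factors, CDK inhibitors and cyclins, the BCL2 family, MHC class I, NF-kappa-B, deacetylases with their co-repressors, neuronal genes, and lysosome and autophagy genes shifted in no comparison with control (camera adjusted p from 0.0793 to 0.958).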
